A study of Homo sapiens with 12 samples.

How the data were processed

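Total RNA from 12 THP-1 cultures was labelled with biotin and hybridised to Illumina expression bead arrays, per the labels. The samples fall into 6 groups, 3 CRISPR targets by 2 viruses, with 2 arrays each. The values used were the log2 expression values that the authors deposited for 47323 probes, which run from 6.69 to 14.8. The quartiles of the 12 arrays differ by no more than the third decimal, with medians near 7.17, as quantile normalization leaves them. The scanner software, the normalization method and whether background was subtracted are not given in the sources used here. A second deposited table of raw intensities and detection p-values holds 24 columns whose names match no sample label, and these were not used.

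The planned fit was to start from those raw intensities, with limma's neqc normalization and a filter on detection p. Because the columns could not be tied to samples, limma was run on the deposited log2 values instead, and a probe was kept when its value lay above 7.29 on at least 2 arrays. That level is the 95th percentile of a background distribution made by mirroring the values below the commonest level. It kept 20177 probes, and the signal of dim genes above background stays uncertain to that extent.

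Probe names came from the platform annotation, updated through gene identifiers with a RefSeq gene table of assembly GRCh38, which was used for names and for which genes neighbour each other. Of the probes, 30113 had 1 gene symbol, 8 had several and 17202 were not listed; the gene identifier was found in the gene table for 30074 probes. Of the kept probes, 15068 had 1 symbol, and each gene was represented by its kept probe with the highest mean, giving 11313 genes, 2968 of which had more than 1 kept probe. Of 64 named genes with several kept probes, 9 had probes that differed in sign for the mean KLF4 effect, CD79B, CREB1, FOXP1, HLA-DRA, KIF23, KLF3, NUF2, TGM5 and ZMAT3.

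A linear model with 1 mean per group was fitted to all 12 arrays with lmFit and eBayes (limma 3.58.1, R 4.3.3), which leaves 6 residual degrees of freedom. There were 10 comparisons: the KLF4 effect as a mean over targets and within each of the 3 targets, the difference of that effect between each edited target and non-targeting lines, and each edited target against non-targeting lines within each virus. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. For 25 gene lists, of which 24 had at least 5 tested genes, camera was run with a preset correlation of 0.01 and again with an estimated correlation, beside fry. Exact two-sided permutation tests were used for the KLF4, CDKN1A and MYB probes. They ran over all 924 splits of the 12 arrays and used neither the pairing by line nor the CRISPR target. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

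Genes were named by a rule fixed before the data were examined. It takes KLF4, CDKN1A, MYB and MIR150 where tested, the 10 largest rises and falls for the mean KLF4 effect with the same sign in all 6 lines, the 5 largest each way in other comparisons, and the 3 smallest p-values each way where none passed. It also takes the 4 members of each list with the smallest p, and 3 from each of 5 lists in the CRISPR comparisons. The neighbours of CDKN1A were chosen after their values were seen.

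The labels name the same CRISPR line for an ECV and a KLF4 array, so the lines pair these samples across viruses. The deviations of same-line arrays from their group means correlated weakly across genes, at 0.0988 for non-targeting, -0.0502 for miR-150 and 0.0713 for p21. The fit without the line was the main one, and the fit with the line as a block an alternative. The other alternatives were another background correction, normalization, filter, choice of probe or variance model, array weights, a 2-fold threshold, and leaving out each array in turn.

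The fits were tested on simulated data with 100 changed genes of each size among 11313. The simulated noise was independent between genes and, for each gene, equal in all groups. For the mean KLF4 effect, 100% of genes were recovered at a log2 change of 0.5 and of 1. For the KLF4 effect in non-targeting lines the shares were 85% and 100%, for the difference of KLF4 effects between p21 and non-targeting lines 29% and 99%, and for p21 against non-targeting lines with KLF4 81% and 100%. A search for runs of low neighbouring genes first used window medians and missed a planted run of 10 genes by more than the tolerance of 2 genes set for the test. It was changed to window means, which placed the run within that tolerance, and all reported values come from window means. The low stretch after CDKN1A had by then been seen with medians.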

Results

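Gene expression was measured on 12 bead arrays in THP-1, a human monocytic leukaemia line. The cells carried CRISPR constructs against miR-150, against p21 (the protein of CDKN1A, an inhibitor of cyclin-dependent kinases) or a non-targeting construct, with 2 lines per target. The non-targeting lines are NT-2 and NT-3, the miR-150 lines are numbered 3 and 4, and the p21 lines are p21-2 and p21-3. Each line received a lentivirus carrying KLF4, a zinc finger transcription factor, or an empty control virus (ECV). RNA was taken 5 days after infection, and the CRISPR cells were 17 days past selection. Each of the 6 groups thus holds 2 arrays, and this small number limits the precision of every comparison. Nothing states that the 2 lines of a target were separate cultures from the start, so the p-values measure the spread between these lines, which may in part be technical. After the filter on dim probes, 11313 genes were tested.

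The targeted and delivered genes were read first. CDKN1A mRNA in p21 lines was lower than in non-targeting lines by a log2 difference of -0.19 with ECV (SE 0.202, adjusted p = 0.988) and -0.84 with KLF4 (SE 0.202, adjusted p = 0.222), and neither difference passed the test. With KLF4 virus the log2 level was 12.07 ± 0.574 (SD, n = 2) in non-targeting lines and 11.23 ± 0.208 (SD, n = 2) in p21 lines. The difference with KLF4 was -1.25 and passed the test without the NT-3 array with KLF4, and was -0.44 without the NT-2 array with KLF4. An edited gene can keep its mRNA, so these levels do not check the edit. MIR150 has no probe in the table used. The pair of probes for KLF4 gave dim signals, at mean log2 levels of 7.80 and 7.80 with ECV, and did not rise on average with the KLF4 virus. They differed by -0.10 (exact permutation test, two-sided p = 0.242, n = 6 per virus) and by -0.23 (exact permutation p = 0.002165, the smallest that 924 splits can give in a two-sided test). The first probe fell from 7.892 to 7.602 and from 7.973 to 7.558 in miR-150 lines 3 and 4, a fall that passed the limma test. That call ended without any single miR-150 array. The same probe fell less in NT-2 and NT-3, and rose from 7.615 to 7.869 in p21-2 and from 7.628 to 7.636 in p21-3. Where these probes lie relative to the part of KLF4 that the virus carries is not given in the sources used here, so they do not check the virus labels.

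Averaged over the 3 CRISPR targets, the largest rise with KLF4 virus was that of S100A8, a calcium-binding protein of monocytes and neutrophils, which rose 39.3-fold (log2 change 5.30, SE 0.146, adjusted p = 6.3e-12, n = 6 lines). Its partner S100A9 rose by a log2 change of 3.32. CD52, a small surface glycoprotein of leukocytes, rose 24.6-fold. The scavenger receptor CD163, found on monocytes and macrophages, rose 17.6-fold, and the receptors LILRA3 and TREM1 rose 17.9-fold and 14.4-fold. These folds are those of the brightest kept probe, and probes of a gene differed in size. For LILRA3 the log2 change was 4.16 in the probe used and 2.51 in the other kept probe. For CD163 it was 4.14 in the probe used, and 4.09 and 2.92 in the others. With ECV the CD163 and LILRA3 probes used lay near the filter level, so their folds may be too small and their order is not fixed. The integrin ITGAM, the transcription factor NFE2, the steroid-metabolising enzyme AKR1C2 and the lysosomal thiol reductase IFI30 rose by log2 changes between 2.82 and 3.07. CDKN1A itself rose 5.96-fold (log2 change 2.58, SE 0.117, adjusted p = 1.0e-09; exact permutation p = 0.002165).

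**Figure D1:**
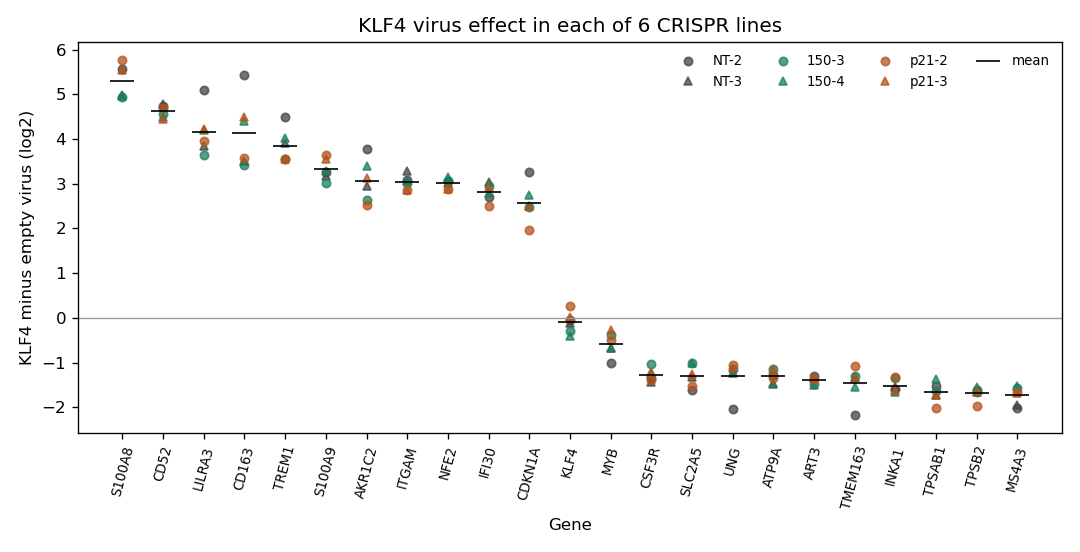
Difference between KLF4 virus and empty virus (log2, vertical axis) in each of the 6 lines for the 10 largest rises, the 10 largest falls, and KLF4, CDKN1A and MYB. Points are lines and black bars the mean; S100A8 has the highest mean at 5.30 and MS4A3 the lowest at -1.74.

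The falls were smaller. MS4A3, a marker of granulocyte and monocyte progenitors, fell by 1.74 on the log2 scale (SE 0.0685, adjusted p = 3.3e-10). The mast cell tryptases TPSAB1 and TPSB2 fell by 1.67 and 1.68, but these are near-identical copies whose probes may not tell them apart. INKA1, TMEM163 and ART3 fell by 1.52, 1.46 and 1.39. The flippase ATP9A, the uracil-DNA glycosylase UNG, the fructose transporter SLC2A5 and the receptor of granulocyte colony-stimulating factor, CSF3R, fell by log2 changes between -1.28 and -1.31; for UNG the change was -2.03 in line NT-2 and between -1.24 and -1.05 in the others. MYB, a transcription factor of immature blood cells and a reported target of miR-150, fell by 0.58 (SE 0.0735, adjusted p = 1.9e-05; exact permutation p = 0.002165). In all, 5023 of 11313 genes changed at an adjusted p under 0.05 (limma), 2215 of them higher and 2808 lower. At least 2-fold changes were mostly rises, with 162 genes higher and 27 lower.

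Gene lists were fixed before the data were examined. Of 28 tested monocyte and macrophage markers, 22 rose and 2 fell (22 and 3 adjusted over the list alone), among them TREM1, ITGAM, the costimulatory CD86 (log2 change 2.55) and the transcription factor CEBPB (1.31). The camera test gave this list an adjusted p of 3.3e-09, and adjusted p = 0.293 with an estimated correlation. Its mean change was 1.34 in line NT-2 and between 0.82 and 0.95 in the other lines. Among lysosome and phagosome genes, 13 of 22 rose and 2 fell (13 and 2 adjusted over the list alone), with the cathepsins CTSH and CTSD higher by 1.22 and 0.99 and the lysosomal proteins PSAP and GRN by 0.92 and 0.77. This list was the single one past the threshold in both forms of the test (adjusted p = 3.3e-06, and adjusted p = 0.0339 with an estimated correlation). Its mean change was 0.52 in line NT-2 and between 0.38 and 0.41 in the other lines. Of 21 leukocyte adhesion genes, 11 rose and 2 fell (12 and 2 adjusted over the list alone; adjusted p = 0.000243, and adjusted p = 0.293 with an estimated correlation), led by ITGAM, ITGB7 (2.77) and PECAM1 (0.78).

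Of 23 NF-kB and inflammatory genes, 16 rose and 4 fell, also when adjusted over the list alone (adjusted p = 0.00176, and adjusted p = 0.444 with an estimated correlation). Examples were IER3 (2.03), the cytokine IL1B (1.26) and the inhibitor NFKBIA (0.95). The mean change of this list was 0.88 in line NT-2 and between 0.28 and 0.40 in the other 5 lines. Of 27 interferon response genes, 15 rose and 4 fell (16 and 4 adjusted over the list alone; adjusted p = 0.000243, and adjusted p = 0.444 with an estimated correlation), such as the antiviral enzymes OAS1 (1.94) and OAS3 (0.61) and the regulator IRF7 (1.54). For the interferon list the mean change was 1.39 in line NT-2 and between 0.35 and 0.55 in the other 5 lines. Of 12 KLF and SP family members, 8 rose and 2 fell, also when adjusted over the list alone (adjusted p = 0.00744, and adjusted p = 0.229 with an estimated correlation), with KLF9 higher by 1.18 and KLF13 by 0.96. The unfolded protein and amino acid stress list had 8 of 19 rise and 2 fall, also when adjusted over the list alone (adjusted p = 0.00744, and adjusted p = 0.344 with an estimated correlation), including DDIT3 (0.80) and ATF3 (0.55). Of 10 lymphoid markers, 4 rose and 0 fell, also when adjusted over the list alone (adjusted p = 0.0155, and adjusted p = 0.235 with an estimated correlation), with the adhesion molecule CD2 higher by 2.28 and NKG7 by 1.17; with no filter on dim probes this list gave an adjusted p of 0.0688.

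Of 27 genes of MYC-driven ribosome biogenesis, 24 fell and 0 rose (25 and 0 adjusted over the list alone; adjusted p = 4.5e-09, and adjusted p = 0.293 with an estimated correlation). MYC itself fell by 1.06 on the log2 scale, ODC1, the first enzyme of polyamine synthesis, by 0.80, and the nucleolar proteins NOP16 and NOP56 by 0.77 and 0.74. The mean change of the list was -0.74 in line NT-2 and between -0.42 and -0.37 in the other 5 lines. Of 32 S phase and DNA replication genes, 23 fell and 2 rose (25 and 2 adjusted over the list alone; adjusted p = 2.7e-05, and adjusted p = 0.444 with an estimated correlation). The replicative helicase subunits MCM2 and MCM5 fell by 0.67 and 0.49 and the cyclin CCNE1 by 0.45, while E2F2 rose by 1.25. Of 14 cholesterol synthesis genes, 7 fell and 0 rose, also when adjusted over the list alone (adjusted p = 0.0454, and adjusted p = 0.293 with an estimated correlation), with LSS lower by a log2 change of -0.74 and IDI1 by -0.45; this call ended with cyclic loess (adjusted p = 0.0671), with normexp background correction (0.0554) and with a strict filter (0.0696). It also ended without NT-3 with ECV (0.0766) or KLF4 (0.0540), miR-150 line 3 with KLF4 (0.0725), or p21-2 with ECV (0.0564) or KLF4 (0.0565).

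The remaining 13 of the 24 lists run did not pass the camera test, which sets a list against all other genes tested. The fry test makes no such comparison, and 22 of the 24 lists passed it. The exceptions were G2 and mitosis (fry adjusted p = 0.374) and glycolysis and hypoxia (fry adjusted p = 0.0561). Adjusted p-values in this paragraph are otherwise those of camera. Genes of G2 and mitosis had 9 of 33 rise and 4 fall (7 and 4 adjusted over the list alone; adjusted p = 0.435), with CDC25B higher by 0.73 and CENPF lower by a log2 change of -0.27. Granulocyte and primary granule genes went both ways, with 8 of 20 higher, such as S100A8, and 7 lower, such as MS4A3 (8 and 8 adjusted over the list alone; adjusted p = 0.674). Cell cycle inhibitors had 4 of 13 rise and 2 fall (adjusted p = 0.189), among them CDKN2D at 1.06 and CDKN2A at -0.44. Of 20 p53 targets 5 rose and 5 fell (adjusted p = 0.438), and CCNG1 fell by 0.58 while CDKN1A rose. Reported miR-150 targets had 4 of 12 rise and 3 fall (5 and 3 adjusted over the list alone; adjusted p = 0.390), with P2RX7 at 1.48 and CXCR4 at -0.81. Ribosomal proteins had 9 of 25 fall and 0 rise (8 and 0 adjusted over the list alone; adjusted p = 0.139), and AP-1 and immediate early genes had 9 of 18 rise and 5 fall (adjusted p = 0.109). The adjusted p was 0.434 for antigen presentation by MHC class II (2 of 7 higher, 2 lower), 0.486 for stem cell and leukaemia genes (3 of 12 higher, 5 lower) and 0.471 for erythroid and megakaryocyte markers (2 of 6 higher, 2 lower). It was 0.189 for apoptosis and the BCL2 family (6 of 18 higher, 2 lower), 0.586 for glycolysis and hypoxia (4 of 23 higher, 7 lower; 4 and 8 adjusted over the list alone) and 0.438 for heat shock (2 of 12 higher, 4 lower). Counts adjusted over the list alone were the same where no second count is given. Epithelial and barrier genes had 4 tested members, too few for the list test, of which LAMB3 rose by 0.86.

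**Figure D2:**
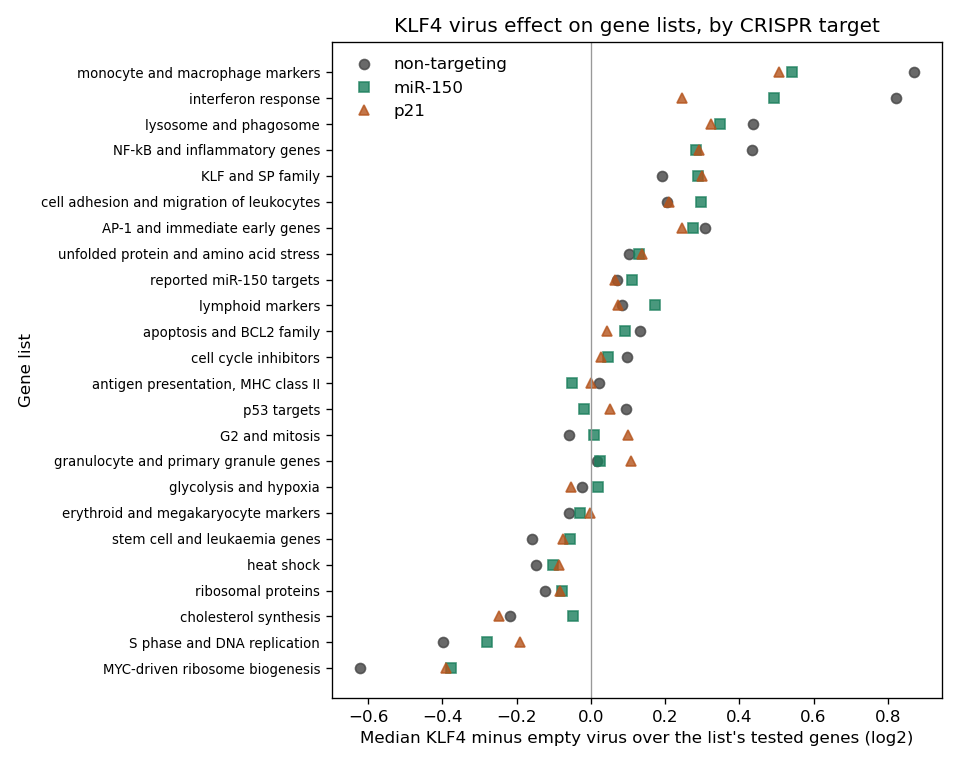
Median difference between KLF4 virus and empty virus (log2, horizontal axis) over the tested genes of each list, with 1 point per CRISPR target. Monocyte and macrophage markers sit highest in all 3 targets, at 0.87 in non-targeting, 0.54 in miR-150 and 0.51 in p21 lines, and MYC-driven ribosome biogenesis lowest, at -0.62, -0.38 and -0.39.

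S100A8, CD52, LILRA3 and CD163 were among the largest rises in non-targeting (log2 changes 5.28, 4.77, 4.47 and 4.47), miR-150 (4.96, 4.52, 3.92 and 3.92) and p21 lines (5.65, 4.57, 4.09 and 4.03). MS4A3, TPSB2 and TPSAB1 were among the largest falls in each. The LILRA3 and CD163 probes used lay near the filter level with ECV, so their rises may be too small in each target. In non-targeting lines the other kept LILRA3 probe rose by 2.88, and the other CD163 probes by 4.43 and 3.28. CDKN1A rose in p21 lines as well, by 2.23 (SE 0.202, adjusted p = 4.9e-06), against 2.88 in non-targeting and 2.61 in miR-150 lines. MYB fell by 0.84 in non-targeting, 0.53 in miR-150 and 0.38 in p21 lines (adjusted p = 0.000285, 0.0101 and 0.0483). The MYB call in miR-150 lines ended without line 4 with ECV (adjusted p = 0.0857) or KLF4 (0.111). That in p21 lines ended in 10 of the 12 fits with 1 array left out, the exceptions being the NT-2 and NT-3 arrays with KLF4, with adjusted p-values from 0.0542 to 0.284; it also ended with normexp background correction (0.0735) and cyclic loess (0.0563). Of 3903 genes called in at least 1 target, 736 rose and 693 fell in all 3. Between non-targeting and miR-150 lines 2 genes were called in opposite directions, and in the other pairs 0. Across genes, the effects correlated between targets with Pearson r of 0.909 for non-targeting with miR-150, 0.885 for non-targeting with p21 and 0.915 for miR-150 with p21 (Spearman rho 0.808, 0.777 and 0.803). These pairs share no array, and genes are not independent replicates. Shared rises numbered 852, 865 and 788, where independent lists would share 126.2, 136.5 and 92.8, and shared falls numbered 851, 941 and 766, where 161.6, 195.2 and 108.3 would be shared.

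The number of genes called within a target was 3264 in non-targeting lines (1449 higher, 1815 lower), 1992 in miR-150 lines (985 higher, 1007 lower) and 2283 in p21 lines (1066 higher, 1217 lower). Lists past the camera test numbered 12, 10 and 11, with lysosome and phagosome genes the single list also past it with an estimated correlation in each (adjusted p = 0.0332, 0.0294 and 0.0313). These gene counts changed with the arrays used. In miR-150 and p21 lines the count was lower whichever array of the comparison was left out. Each such fit leaves a group with a lone array, so these falls do not show that particular arrays carried the calls. The non-targeting count was 2028 without NT-3 with ECV and 1419 from the groups of that comparison alone. The miR-150 count was 920 without line 3 with ECV, 1113 without line 4 with ECV, 1293 without line 3 with KLF4 and 1030 without line 4 with KLF4. The p21 count was 1230 without p21-2 with ECV, 1345 without p21-3 with ECV, 1401 without p21-2 with KLF4 and 1095 without p21-3 with KLF4. The list count in p21 lines was 7 without p21-2 with ECV.

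The study's title names knockouts of miR-150 and p21, which asks whether the response to KLF4 needs either gene. No single gene passed the test of a difference in the KLF4 effect (limma, 0 genes for miR-150 and 0 for p21 against non-targeting lines; 455 and 660 genes at an unadjusted p under 0.05). The smallest p-values belonged to MPDU1 (-0.72, adjusted p = 0.403) and NUF2 (-0.66, adjusted p = 0.972) for miR-150, and to TXNDC5 (0.67, adjusted p = 0.828) and BTK (0.56, adjusted p = 0.828) for p21. For CDKN1A the KLF4 effect differed by -0.65 in p21 lines (SE 0.286, adjusted p = 0.828), and for MYB by 0.45 (SE 0.180, adjusted p = 0.828). Without NT-2 with KLF4 these were -0.25 and 0.24, and without NT-3 with KLF4 they were -1.06 and 0.67. Without NT-3 with KLF4 all 6 differences named here passed the test. In data simulated for the p21 difference, 99% of genes with a log2 difference of 1 and 29% of those with 0.5 were recovered. Smaller differences could thus be missed at this number of arrays. The simulated noise was independent between genes and equal in all groups. In the data the non-targeting group with KLF4 had an SD of 0.198, against 0.0905 in miR-150 lines with ECV, so these shares are a rough guide only.

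Gene lists did differ in the camera test, 7 for miR-150 and 9 for p21. Interferon response genes had the smallest p in both, with a median difference of -0.39 in miR-150 lines (adjusted p = 4.2e-09, and adjusted p = 0.410 with an estimated correlation) and -0.54 in p21 lines (adjusted p = 1.3e-09, and adjusted p = 0.447 with an estimated correlation). With an estimated correlation, and in the fry test, 0 lists differed. These differences rested on 1 array, NT-2 with KLF4, whose spread from NT-3 set the group's SD at 0.198 against 0.0905 to 0.113 in the other 5 groups. Without it, 1 list and 0 lists differed, and the interferon response median was 0.02 (adjusted p = 0.996) for miR-150 and -0.11 (adjusted p = 0.429) for p21. Without NT-3 with KLF4 in its place, which leaves NT-2 alone for that group, 439 and 586 genes differed, against 1 and 2 genes without NT-2 with KLF4. The list count for miR-150 was also 4 without miR-150 line 4 with ECV and 4 without NT-3 with ECV.

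Lines targeted at miR-150 were hard to tell from non-targeting lines. With ECV, 0 genes differed (limma; 370 at an unadjusted p under 0.05), and the reported miR-150 targets with the smallest p were FOXP1 at -0.29, CXCR4 at -0.13 and CREB1 at 0.14 (each adjusted p = 0.9999). CXCR4 was at -0.07 without NT-3 with ECV. MYB differed by 0.02 (SE 0.127), and by -0.03 to 0.08 with 1 array left out. With KLF4, 0 genes differed (607 at an unadjusted p under 0.05), and MYB differed by 0.33 (SE 0.127, adjusted p = 0.840), by 0.11 without NT-2 with KLF4 and by 0.54, past the test, without NT-3 with KLF4. Without NT-2 with KLF4 that count was 3, and without NT-3 with KLF4 it was 1006. Lists past the camera test numbered 2 with ECV, glycolysis and hypoxia (median -0.10, adjusted p = 0.000402, and adjusted p = 0.398 with an estimated correlation) and MYC-driven ribosome biogenesis (median -0.08, adjusted p = 0.0106, and adjusted p = 0.830 with an estimated correlation). They numbered 1 without NT-2 with ECV or miR-150 line 4 with ECV. With KLF4 they numbered 8, against 0 with an estimated correlation (smallest adjusted p = 0.3945) and 0 in the fry test. Fewer than these 8 passed without NT-2 with KLF4 or without miR-150 line 3 with KLF4.

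Few genes differed between p21 and non-targeting lines, and all were lower. With KLF4 these were CCDC167 (log2 difference -0.87, SE 0.138), ZFAND3 (-0.76, SE 0.118), CMTR1 (-0.72, SE 0.114), AAK1, a kinase of clathrin-mediated endocytosis (-0.65, SE 0.0990), and NFKBIE, an inhibitor of NF-kB (-0.58, SE 0.0830), each with an adjusted p of 0.0480. With ECV, AAK1 was the single gene (-0.73, SE 0.0990, adjusted p = 0.0413). Among the S phase, mitosis and cell cycle inhibitor lists, MCM6 (0.32), CENPF (0.41) and CDKN1B (0.35) had higher values with KLF4 that did not pass the test (adjusted p = 0.292, 0.246 and 0.325). Without NT-3 with KLF4 they were at 0.44, 0.55 and 0.51, and without NT-2 with KLF4 MCM6 was at 0.21 and CDKN1B at 0.19. The other kept CDKN1B probe had a like mean level, 9.49 against 9.55 in the probe used. Its KLF4 effect in non-targeting lines was 0.16, against -0.22 in the probe used, so the CDKN1B difference may depend on the probe. These calls were marginal: with each of the 12 arrays left out, the KLF4 count ranged from 0 to 1438, with 17 genes without NT-2 with KLF4, 1438 without NT-3 with KLF4 and 0 without any other array. With the line as a block the KLF4 count was 0. The ECV count was 28 without either non-targeting array with KLF4 and 0 without any of the other 10 arrays, where AAK1 had an adjusted p from 0.0707 to 0.488. With ECV 0 lists shifted, against 1 with the line as a block and 1 without NT-2 with KLF4, NT-3 with KLF4, miR-150 line 3 with KLF4, miR-150 line 4 with KLF4 or p21-2 with ECV. With KLF4, 11 lists passed the camera test, 0 with an estimated correlation and 0 without NT-2 with KLF4.

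CCDC167, ZFAND3 and CMTR1 lie next to each other on chromosome 6, in a run of genes that follows CDKN1A. This stretch was looked at after those values were seen. Where AAK1 and NFKBIE lie relative to the low genes described below is not reported here. Their calls are thus not read as changes separate from the stretch. All 10 tested genes that follow CDKN1A were lower in p21 than in non-targeting lines, averaged over both viruses, with a mean log2 difference of -0.41 (SE 0.0446 over genes). They include PPIL1 (-0.42), MTCH1 (-0.35), the kinase PIM1 (-0.42), TBC1D22B (-0.45), the ubiquitin ligase RNF8 (-0.51) and CMTR1 (-0.63). The mean was -0.43 in p21-2 and -0.39 in p21-3, and -0.34 with ECV and -0.48 with KLF4. The 10 tested genes before CDKN1A had a mean difference of 0.01 (SE 0.0315), and SRSF3, next to CDKN1A on that side, was at 0.18. In the miR-150 lines the 10 genes after CDKN1A had a mean difference of -0.05 (SE 0.0243). Past ZFAND3 the shift was smaller but went on: of the 48 tested genes from GLO1 to POLR1C, 42 were lower in p21 lines, with a mean of -0.17 (SE 0.01997), against 23 lower and a mean of 0.00 (SE 0.00929) in miR-150 lines. GLO1 was at 0.01, NFYA at -0.28, BYSL at -0.36 and MEA1 at -0.53. In consecutive blocks of 10 tested genes, the mean in p21 lines was -0.23 in the block from HSP90AB1 to TDRD6, -0.10 (SE 0.0635) in the next block, which starts at TNFRSF21, and -0.01 in the block from TMEM14A to HMGCLL1.

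**Figure D3:**
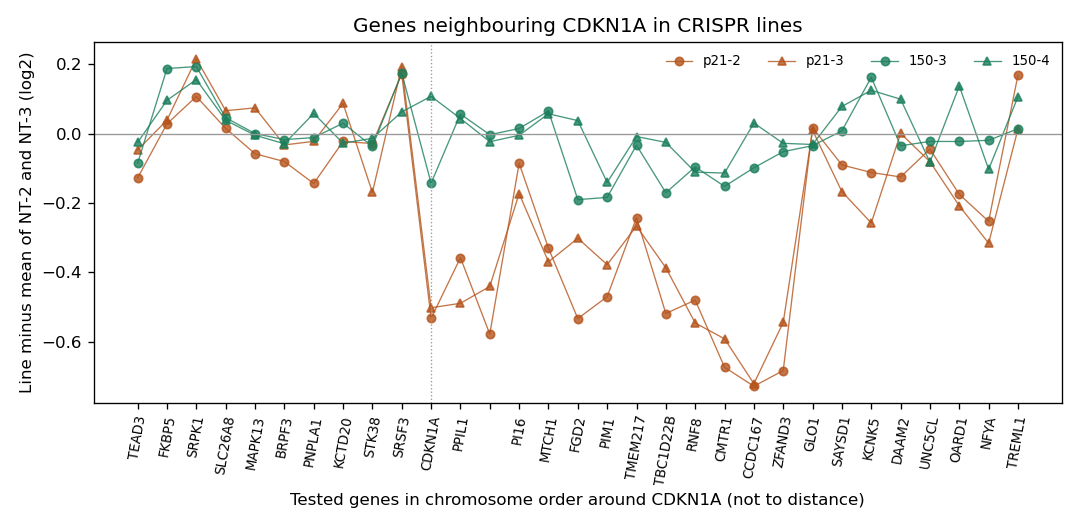
Difference of each p21 and miR-150 line from the mean of both non-targeting lines (log2, vertical axis, mean of both viruses) for tested genes in chromosome order around CDKN1A (horizontal axis, not to distance; a gene without an established name has no label). In both p21 lines the values drop at CDKN1A, at -0.53 and -0.50. Past ZFAND3 they vary, with GLO1 at 0.02 and 0.01 and NFYA at -0.25 and -0.32. For CDKN1A itself the mean of both p21 lines was -0.19 with ECV and -0.84 with KLF4.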

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

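Of the tests in this part, the comparison of spread at dim probes was chosen before its result was seen, and the trend with the KLF4 effect, the interferon percentile and the count of lists outside random ones after. The difference between KLF4 and ECV arrays was examined in the 6 lines for 47 genes and lists, and in 9 of them 1 line lay apart (gap over range above Dixon's 95% critical value; chance alone gives about 1 in 20). Line NT-2 was the one apart for 7 of these. For UNG it stood at -2.03 against -1.24 to -1.05 elsewhere (ratio 0.802). For list means it stood at 1.34 against 0.82 to 0.95 for monocyte and macrophage markers (0.743), and at -0.74 against -0.42 to -0.37 for MYC-driven ribosome biogenesis (0.868). The values were 1.39 against 0.35 to 0.55 for interferon response (0.807) and 0.88 against 0.28 to 0.40 for NF-kB and inflammatory genes (0.790). They were 0.52 against 0.38 to 0.41 for lysosome and phagosome genes (0.796) and 0.50 against 0.20 to 0.31 for AP-1 and immediate early genes (0.640). Line p21-2 lay apart for TPSB2 (-1.97 against -1.66 to -1.55, ratio 0.745) and for heat shock genes (0.05 against -0.10 to -0.05, ratio 0.655).

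Several gene lists had a KLF4 effect that differed from non-targeting lines in the camera test. In miR-150 lines the adjusted p was 0.00226 for monocyte and macrophage markers, 0.0231 for antigen presentation, 0.000381 for NF-kB and inflammatory genes and 4.2e-09 for interferon response, all lower. It was 0.0190 for S phase, 7.9e-06 for MYC-driven ribosome biogenesis and 0.0468 for cholesterol synthesis, all higher. In p21 lines it was 0.000181 for monocyte and macrophage markers, 0.0290 for antigen presentation, 1.3e-09 for interferon response, 0.000116 for NF-kB and inflammatory genes, 0.0324 for apoptosis and 0.0358 for leukocyte adhesion, all lower. It was 0.00225 for S phase, 0.00833 for G2 and mitosis and 3.95e-05 for MYC-driven ribosome biogenesis, all higher. With an estimated correlation none of these passed, the smallest adjusted p being 0.410 and 0.420.

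The NT-2 array with KLF4 underlies most of both patterns. Random array noise, independent between genes, is argued against as the whole cause. With the trend on the KLF4 effect removed, 8 of 24 lists had a median outside 95% of random lists. Of 1000 shuffles of genes of like level, 0 gave as many (at most 6). Several of these lists had already been seen apart in NT-2. Shuffling also breaks shared changes of genes, so a technical shift of many genes together was not covered. A noisier array as part of the cause stays open. The SD of NT-2 with KLF4 about the other arrays at 22602 dim probes was 0.0822, the highest of the 12 but close to the next at 0.0809. A stronger response to KLF4 in that culture was not settled, since NT-2 minus NT-3 with KLF4 correlated with the KLF4 effect in the edited lines at 0.392 across genes. The interferon response list was at percentile 100 of 10000 random lists, as were monocyte and NF-kB lists, but it was picked because NT-2 stood apart on it, so this decides nothing about a separate interferon response, and culture or virus preparation were not tested.

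Of 5107 probes past the filter that are not named here, 1249 changed with KLF4, 463 higher and 786 lower.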

How the results depend on the processing

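The 2-fold threshold, array weights and leaving out both NT-2 arrays were chosen after seeing the data; the other alternatives, among them the replicate block, were chosen before. Of the settings compared, 448 values of counts, levels and correlations were classed as unchanged, 124 as moved and 1 level as stronger. Unchanged meant within 1.5 times for counts and within the SD over pairs of lines for correlations. For levels it meant the same direction and side of the threshold, whatever the size. Of the values of named genes, 5813 kept direction and side of the threshold, 163 lost the call, 47 gained one and 25 reversed. All groups share 1 estimate of the spread, so leaving out an array outside a comparison changed that estimate and not the comparison's means. For p21 against non-targeting lines with ECV this holds for the non-targeting arrays with KLF4, whose SD was 0.198. For the rest of the following the cause was not tested, except that fewer arrays or genes were tested. For p21 against non-targeting lines with KLF4 the count was 0 with normexp, cyclic loess, the groups of the comparison alone, the replicate block, array weights, the 2-fold threshold or every kept probe tested on its own, 1 with no filter and 21 without both NT-2 arrays. With ECV it was 0 with cyclic loess or the 2-fold threshold, 2 with no filter, 17 from the groups of the comparison alone, 14 with array weights and 13 without both NT-2 arrays; the lists there numbered 1 with cyclic loess, no filter or the replicate block. The pairing by line changed no other count by more than 1.5 times. The KLF4 count in non-targeting lines was 1419 from its own groups alone. Without both NT-2 arrays the KLF4 count was 2030 in non-targeting and 3048 in miR-150 lines, the KLF4 effect differed for 1 gene in miR-150 and 1 in p21 lines, 2 (ECV) and 3 (KLF4) genes differed for miR-150, and lists numbered 1 and 0 for the differences of the KLF4 effect and 1 and 0 for miR-150 and p21 with KLF4. At least 2-fold, 189, 277, 180 and 170 genes changed (mean, non-targeting, miR-150, p21). With an estimated correlation 1 list passed in each of these and 0 in every other comparison; fry gave 22 for the mean, 19 for non-targeting lines and 0 for the differences and CRISPR comparisons. Correlations (non-targeting with miR-150, non-targeting with p21, miR-150 with p21) were 0.877, 0.854 and 0.878 with no filter, 0.863 and 0.851 for the first pairs without both NT-2 arrays, and for the last 0.894 with normexp and 0.926 with the strict filter. Leaving out 1 array each time, where a lone array is assumed to vary like the other groups, gave 4423 to 5680 genes for the mean, 2028 to 4234 in non-targeting, 920 to 2940 in miR-150 and 1095 to 3149 in p21 lines; 0 to 439 and 0 to 586 for the differences; 0 to 28 and 0 to 1438 for p21 with ECV and KLF4; 0 to 1006 for miR-150 with KLF4. Lists ranged over 7 to 12 in p21 lines, 1 to 9 and 0 to 9 for the differences, 1 to 3 and 1 to 8 for miR-150 with ECV and KLF4, 0 to 1 and 0 to 11 for p21; correlations over 0.860 to 0.909, 0.828 to 0.885 and 0.885 to 0.915; CDKN1A in p21 lines with KLF4 over -1.25 to -0.44. Values that reversed, none past the threshold where reversed, ranged as follows. For the mean, ALPI -0.085 to 0.0031 (0.010 without both NT-2 arrays) and DSP -0.084 to 0.022. In non-targeting lines, KLF4 -0.19 to 0.023, IL7R -0.075 to 0.42 (-0.027 without both NT-2 arrays), ALPI -0.051 to 0.12 and SPRR1A -0.055 to 0.077. Against non-targeting lines, for miR-150, CDKN1A -0.67 to 0.14 for the difference (0.11 without both NT-2 arrays) and -0.56 to 0.25 with KLF4 (0.25), MYB -0.027 to 0.075 with ECV (-0.027) and CDKN2D -0.62 to 0.030 with KLF4 (0.030); for p21, MYB -0.10 to 0.082 with ECV and KLF4 -0.12 to 0.11 with KLF4 virus (0.10). Planned but not run were no background correction of raw intensities and the slide as a block, since raw columns match no label and no slide is given; the deposited values became the data used. Signal near background limits dim genes.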

Other observations

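All tests on the CDKN1A neighbourhood in this part were chosen after the values were seen, and the splits of the arrays before. Across the genome, the run of 10 neighbouring genes with the lowest mean in p21 against non-targeting lines was the run from PI16 to ZFAND3 on chromosome 6, at -0.45, and it was the lowest run in p21-2 (-0.48) and in p21-3 (-0.43) taken alone. Among 1000 shuffled gene orders, 0 shuffled orders held a run as low, and the lowest was at -0.24 (shuffling also breaks any shared regulation of neighbours), which argues against a chance run of low genes. Against non-targeting lines being high there, the 10 genes after CDKN1A were lower in p21 than in miR-150 lines by a mean of -0.36. Against an event in one line, the mean in the p21 line with the smaller shift was -0.39.

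A candidate explanation is a stretch of chromosome 6, starting at the guide's target in CDKN1A, that was partly lost or silenced in the p21 lines. Whether all or a share of the cells would be affected was not tested. The 10 genes after CDKN1A had a mean 0.42 lower than the 10 genes before it (difference -0.42), which this hypothesis needs but which was found on the same data. Past ZFAND3, 42 of the next 48 tested genes were lower, with a smaller mean of -0.17, and the mean per block of 10 genes was -0.23 from HSP90AB1 to TDRD6, -0.10 (SE 0.0635) in the next block, from TNFRSF21 on, and -0.01 from TMEM14A to HMGCLL1. A single step of even depth does not describe this, and why the genes up to ZFAND3 were lower than the later ones was not tested. The means beside MIR150 in miR-150 lines, -0.0736 (SE 0.0265) and -0.0393 (SE 0.0364), argue against low neighbours of this size around any CRISPR target. With its SE the first reaches the bound set for exclusion, so a small effect is not excluded. In miR-150 line 4 the lowest run of 10 neighbouring genes in the genome was on chromosome 19, from POLD1 to CTU1, at -0.12. In miR-150 line 3 it was on chromosome 17, from RHBDL3 to LIG3, at -0.20. The distance of the chromosome 19 run from MIR150 is not given here, so a small shift farther from MIR150 is not excluded. NT-2 was higher than NT-3 at the 10 genes after CDKN1A, by a mean of 0.19. A loss already present in the parent cells of both p21 lines, and a response of these genes to loss of p21, were not tested. DNA copy number across the stretch would part a loss from silencing or a response to loss of p21, and the parent cells would be needed to date a loss.

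For the mean KLF4 effect, 100 splits of the 12 arrays into 6 and 6 were fitted with 2 groups each, all 32 that part the arrays of every line and others drawn at random. The real split gave 5055 genes and the highest other split 1113, so 1 of the 100 splits, the real one, gave as many. This argues against chance but cannot exclude it, as 1 in 100 is the smallest share this test can give. Among the other splits that part every line the highest gave 0 genes. Other splits leave the difference between viruses in the spread, so their low counts are no separate support.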
